A study of Mus musculus with 12 samples.

How the data were processed

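RNA was sequenced from whole mouse liver in 12 libraries, 3 for each combination of genotype (wild type, WT, or a hepatocyte knockout of Sirt2, KO) and injected plasmid (GFP, or the oncogenes MET and beta-catenin, MET/CAT). Per the labels' protocols, plasmids were injected with a transposase through the tail vein under pressure, mice were 6 to 8 weeks old at injection, and livers were taken 8 weeks later. Groups follow the sample titles. The labels' treatment field follows the genotype instead, naming GFP for every WT library and MET/CAT for every KO library, so that it contradicts the titles of the KO GFP and the WT MET/CAT libraries. The series title speaks of livers given either plasmid in connection with the Sirt2 deletion, as the sample titles do, and the direction of each comparison rests on the titles. The labels do not state outright that each replicate is a different mouse, so p-values measure the spread between these libraries.

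Per the submitters' processing notes, HISAT2 2.0.4, HTSeq 0.11.2 and the mouse build GRCm38 were used. The library kit, its strand setting and the normalization tool are not given in the sources used here, and so overlapping and antisense genes may share reads. The deposited values are a signal per gene, namely gene counts divided by 1 factor per library. In each library the values were whole multiples of 1 step, and the step differed between libraries from 0.753 to 1.204 normalized units per read. Dividing by the step gave whole reads for 100% of the values, with a departure of at most 0.000371 reads. In WT GFP replicate 1 and WT MET/CAT replicate 1 the step lies so near to 1 that whole-number values were not claimed as proof of recovered reads. The recovered libraries held 18208879 to 24352961 reads. The deposited factors lay within 0.954 to 1.05 times the median-ratio factors computed from the recovered reads. The table holds 47263 genes, of which 23020 had no read in any library. Gene positions came from GENCODE M21 on the same build, where 47191 symbols were found. A set of 26 date-like names and 2 names used more than 1 time were never named.

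The unit was not raw counts, and so the main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(value + 1). Genes needed a value of at least 10 in at least 3 libraries, which 13871 genes met. A single linear model with 4 group means was fitted over all 12 libraries, without a block. Contrasts gave the genotype effect within each plasmid, the plasmid effect within each genotype, the interaction and the genotype effect averaged over plasmids. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Where a group had no read, a fold is a lower bound against a floor of 3 reads over the group, and a fold against few reads has a 95% Poisson interval. Floors and intervals cover counting error only. Per library, a count of 0 allows a value of up to 2.26 to 3.61 normalized units.

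A total of 38 gene lists, written from general knowledge of liver, MET and beta-catenin tumours and cell types, were tested with limma's camera at a preset correlation of 0.01. Lists needed at least 4 measured genes, and adjusted p were taken over the 36 tested lists within each comparison. Camera was repeated with an estimated correlation. Lists, tests, groups and the rule for named genes were fixed before the data were examined. Counts of members that passed when adjusted over the list alone, by Benjamini-Hochberg within that list, were not among those tests. They are not corrected over the lists or over all genes, and are given mostly for lists that camera had called. They describe a list and are no separate support for it. The rule took Sirt2, Met, Ctnnb1, Glul, Axin2 and Lgr5 in every sample. It took up to 10 higher and 10 lower called genes per comparison by size of change, with a mean of at least 100 in the highest group and no overlap between the libraries compared, which chance gives for 10% of genes. Predicted genes, pseudogenes and receptor segments were left out there. With fewer than 5 calls, the 5 smallest p were given as values. For each list described, up to 4 members with the smallest p were named, and all called members where 5 or fewer were called. A few genes that meet this rule are not reported here.

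Alternatives fixed beforehand were other pseudocounts and filters, quantile normalization, equal library totals, library quality weights, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, a replicate block, a fit of the 6 libraries compared, and each library left out in turn. Alternatives added after the data were seen were removal of each library's trend with transcript length (ordinary loess, robust loess, and ordinary loess with length and GC content together) and an exact permutation of 1 score per list and library. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

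The model was tested on simulated data in which 67, 67 and 66 genes were changed 2-, 4- and 8-fold. For KO against WT in GFP livers (13646 genes) limma recovered 31.3%, 83.6% and 93.9% of them, with 7 false among 146 calls. For MET/CAT against GFP in WT livers (13653 genes) it recovered 16.4%, 92.5% and 98.5%, with 11 false among 149 calls. For the interaction (13661 genes) it recovered 1.49%, 68.7% and 87.9%, with 4 false among 109 calls. No recovered gene had the wrong sign. The changed genes were drawn only from genes with means well above the filter, and the simulated libraries held no length trend or other structure. So many planted changes also ease the Benjamini-Hochberg threshold, compared with real data where few genes differ. The recovered shares may therefore overstate the power in the real comparisons. In a simulated average over plasmids, camera called a 1.5-fold shift of the interferon list (adjusted p = 3.06e-25) and none of the 35 other lists, but simulated genes vary independently and real ones do not.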

Results

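The series measured gene expression by RNA sequencing in whole mouse livers with or without hepatocyte Sirt2, 8 weeks after injection of a GFP plasmid or of MET/CAT plasmids, a model of liver cancer. It asked what Sirt2 contributes to tumour formation by these oncogenes. Each of the 4 groups, WT GFP, KO GFP, WT MET/CAT and KO MET/CAT, had 3 libraries of 18208879 to 24352961 recovered reads, and a single read was worth 0.753 to 1.204 normalized reads. The 10 most abundant genes took 19.7% to 25.4% of the reads. No replicate pair was so alike as to be 1 library deposited again. KO GFP replicate 3 stood apart from the rest on the first principal component (21.96% of the variance), at −88.95 against −33.2 to 52.8 in the other libraries. It also had the strongest trend of expression with transcript length (Spearman rho = 0.471 across genes, which are not independent replicates).

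Sirt2 (chromosome 7, 28766735 to 28788661, GRCm38), an NAD-dependent deacetylase and the targeted gene, was lower in all 6 KO libraries than in all 6 WT libraries. Normalized reads were 823.7, 923.6 and 725.8 in the WT GFP libraries and 232.6, 182.5 and 125.7 in the KO GFP libraries. They were 1068, 942.7 and 908.4 in the WT MET/CAT libraries and 248.1, 234.3 and 200.6 in the KO MET/CAT libraries. Sirt2 fell by 2.22 (log2, SE 0.23) in KO GFP livers (limma adjusted p = 0.00189) and by 2.09 in KO MET/CAT livers (SE 0.23, adjusted p = 0.00394). The first call ended when only the 6 GFP libraries were fitted (adjusted p = 0.106), and the second without KO MET/CAT replicate 3 (−2.005, adjusted p = 0.0526). The table gives 1 value per gene over all exons, and the deleted exons are not given in the sources used here.

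Of Met, Ctnnb1 and the beta-catenin targets Glul, Axin2 and Lgr5, only Glul in KO livers passed the test of MET/CAT against GFP. Met (chromosome 6, 17463800 to 17573980), the receptor of hepatocyte growth factor, had means of 785.7 ± 46.3, 1251 ± 374, 763.7 ± 174 and 724.2 ± 124 normalized reads (SD, n = 3) in WT GFP, KO GFP, WT MET/CAT and KO MET/CAT livers. Its MET/CAT to GFP difference was −0.06 in WT (adjusted p = 0.92) and −0.76 in KO livers (adjusted p = 0.116). Ctnnb1 (chromosome 9, 120929216 to 120960507), which encodes beta-catenin, differed by 0.24 in WT (adjusted p = 0.77) and −0.49 in KO livers (adjusted p = 0.417). The species of the plasmid cDNAs, and so whether their reads can map to the mouse genes, is not given in the sources used here. Glul (chromosome 1, 153899944 to 153909723), glutamine synthetase of pericentral hepatocytes, averaged 19110 ± 3300 in WT GFP and 53310 ± 14300 in WT MET/CAT livers (SD, n = 3), a difference of 1.45 (SE 0.30, adjusted p = 0.0529). It rose from 19600 ± 1890 to 63880 ± 24000 in KO livers (1.63, SE 0.30, adjusted p = 0.0222), a call that held in 1 of the 6 fits leaving out a library. Axin2 (chromosome 11, 108920349 to 108950783) differed by 1.66 in WT (57.1 ± 21.4 to 174.0 ± 24.5, adjusted p = 0.0679) and 0.68 in KO livers (adjusted p = 0.311). Lgr5 (chromosome 10, 115450311 to 115587780), a receptor for R-spondins, differed by 0.31 (adjusted p = 0.737) and 0.96 (adjusted p = 0.181).

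**Figure D1:**
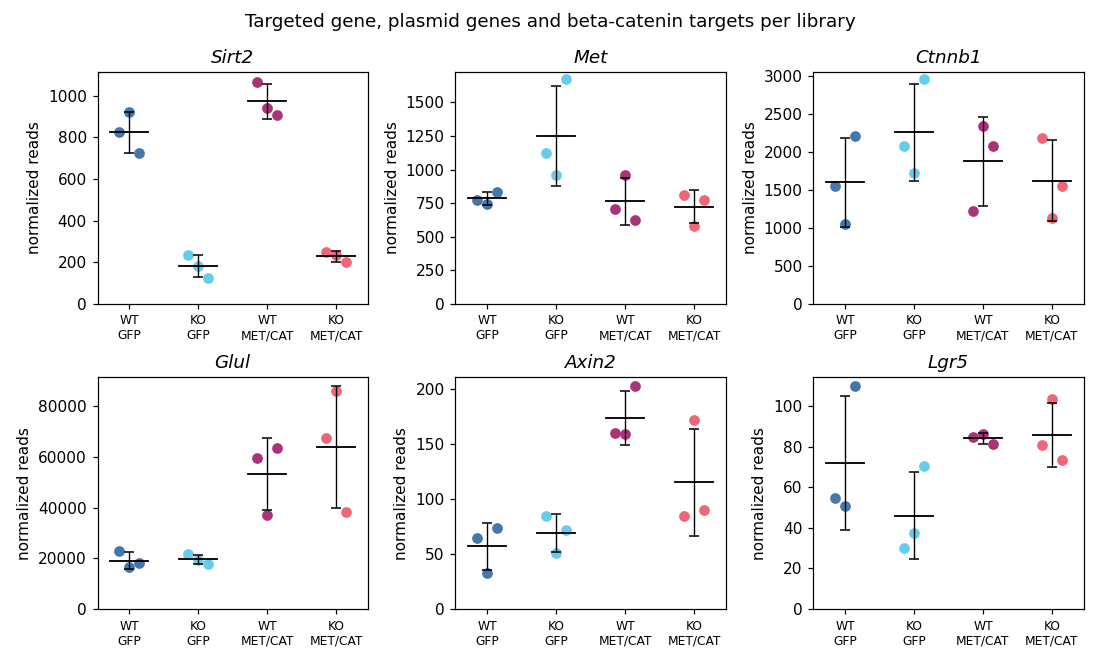
Normalized reads (vertical axes, linear, from 0) of Sirt2, Met, Ctnnb1, Glul, Axin2 and Lgr5 in the 4 groups, where points are libraries, horizontal lines are means and bars are ± 1 SD (n = 3). Sirt2 lay at 125.7 to 248.1 in the 6 KO libraries and at 725.8 to 1068 in the 6 WT libraries.

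In GFP livers, the comparison of KO with WT asked what the loss of Sirt2 changed without oncogenes. Sirt2 was the single gene called. Among the next genes by p, the predicted gene Gm44291 differed by −3.12 (adjusted p = 0.0858), with 137 reads in the WT and 15 in the KO libraries (ratio 0.0958, 95% interval 0.0522 to 0.164). The zinc finger gene Zfp791 averaged 10.8 ± 6.41 in WT and 128.9 ± 16.0 in KO livers (SD, n = 3; 3.60, SE 0.58, adjusted p = 0.0859), and Cotl1, an actin-binding protein, differed by −1.28 (adjusted p = 0.107). Among 13871 genes limma called 0 higher and 1 lower, edgeR 0 and 1, and DESeq2 47 and 61, while 2155 genes had an unadjusted p under 0.05 against 693.6 by chance. Without KO GFP replicate 2, 10 genes were called.

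Macrophage and Kupffer cell markers were lower in KO than in WT GFP livers. Of 25 measured, 23 had lower values and none was called over all genes, while 17 fell when adjusted over the list alone. The median was −1.25 (camera adjusted p = 3.56e-09, and adjusted p = 0.495 with an estimated correlation). Laptm5, a lysosomal protein of leukocytes, differed by −1.29 (510.5 ± 15.3 to 211.3 ± 42.7), Clec4f, a Kupffer cell lectin, by −1.86 (2792 ± 572 to 856.5 ± 436), Aif1 by −1.40 and C1qa, a subunit of complement C1q, by −1.88. KO GFP replicate 3 was the lowest library for this list, with a mean log2 deviation of −1.65 against −0.42 and −0.60 in the other KO GFP livers, and the median without it was −0.74. Antigen presentation genes had a median of −0.62 over 16 measured (adjusted p = 2.51e-05; 0.495 as the adjusted p with an estimated correlation), and 7 fell when adjusted over the list alone. Among them were the class II genes Cd74 (−1.26), H2-Ab1 (−1.09) and H2-Aa (−1.02), and the class I loading factor Tapbp (−0.66). KO GFP replicate 3 was lowest here too, with a mean log2 deviation of −0.998 against −0.16 and −0.25 in the other KO GFP libraries. Interferon response genes had a median of −0.63 over 37 measured (adjusted p = 6.86e-06; adjusted p = 0.495 with an estimated correlation), and 5 fell when adjusted over the list alone. Isg15, a ubiquitin-like modifier, differed by −1.22, the immunoproteasome subunit Psmb8 by −1.35, Ifit3 by −1.17 and Oasl1 by −1.05.

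Metabolic and growth genes also separated by list in GFP livers. The 35 measured cell cycle genes had a median of 1.15, with 33 higher values and none passing over the list alone (adjusted p = 6.71e-09; adjusted p = 0.495 with an estimated correlation). Pcna, the sliding clamp of DNA replication, differed by 0.67 and Rrm2 by 1.15, while the replication helicase genes Mcm5 (2.01) and Mcm6 (1.34) turned to −0.05 and −0.14 with library quality weights. Mean log2 deviations of the cell cycle list overlapped between the groups, at 0.74, −1.10 and −0.90 in WT GFP and −0.20, 0.94 and 1.197 in KO GFP replicates 1 to 3, and the median was 1.72 without WT GFP replicate 1, 0.66 without WT GFP replicate 2 and 0.73 without KO GFP replicate 3. Oxidative phosphorylation genes had a median of −0.54 over 38 measured, again with none passing over the list alone (adjusted p = 2.68e-06; adjusted p = 0.557 with an estimated correlation). The complex I subunits Ndufb10 (−1.02), Ndufb5 (−1.08), Ndufs7 (−1.12) and Ndufa2 (−1.26) led this list. KO GFP replicate 3 had a mean log2 deviation of −0.99 there against −0.08 and 0.12 in the other KO GFP and 0.01 to 0.49 in the WT GFP libraries, and the median without it was −0.22 (adjusted p = 0.0302). Log2 fold changes in this comparison rose with transcript length (rho = 0.394 across genes), and with the length trend removed the list's median was −0.08 (adjusted p = 0.182), and under quantile normalization it was −0.36. Urea cycle and amino acid genes had a median of −0.43 over 37 measured, and 5 fell when adjusted over the list alone (adjusted p = 0.00123; adjusted p = 0.495 with an estimated correlation). This call ended under quantile normalization (−0.18, adjusted p = 0.0767), and the median was −0.25 with equal totals and −0.27 with the length trend removed. Glycine N-methyltransferase Gnmt differed by −0.98 (85520 to 43190), Hpd by −0.88, the cystathionine synthase gene Cbs by −0.68 and Gpt by −0.79. These list calls rest on the preset correlation of camera, and other splits of the same 6 libraries called up to 18 lists against the real 15.

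In MET/CAT livers, the comparison of KO with WT asked what Sirt2 loss changed after oncogene injection. Sirt2 was again the single gene called, by limma (0 higher, 1 lower) and edgeR (0 and 1), whereas DESeq2 called 8 and 27, and 1076 genes had an unadjusted p under 0.05 against 693.6 by chance. The next genes by p, all at an adjusted p of 0.495, were mt-Co2 and mt-Co3, mitochondrially encoded subunits of cytochrome c oxidase, at −1.25 (1932 ± 510 to 804.7 ± 158, SD, n = 3) and −1.11. They were followed by Zbp1, an interferon-induced nucleic acid sensor, at −1.48 (358.6 ± 64.4 to 131.8 ± 45.6), and Sec61a1 of the protein translocation channel at −0.92. Mitochondrially encoded genes together took 3.36% to 5.83% of the reads in WT and 2.11% to 3.03% in KO MET/CAT libraries. Their share was 1.76% to 3.68% in WT GFP and 2.47% to 3.72% in KO GFP libraries. The KO MET/CAT libraries thus lay in the range of the GFP livers, where KO was not lower than WT, and the WT MET/CAT group was the high one. The count of called genes was 12 without WT MET/CAT replicate 1, 8 without WT MET/CAT replicate 3 and 0 without KO MET/CAT replicate 3.

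Interferon response genes were lower in KO MET/CAT livers. Of 37 measured, 35 had lower values and 13 fell when adjusted over the list alone, with a median of −0.77 (camera adjusted p = 4.4e-14; adjusted p = 0.362 with an estimated correlation). Besides Zbp1, the list was led by Ifit3 (−1.38), Isg15 (−0.995) and Ifit3b (−1.55), and Ifit3 and Ifit3b are near-identical copies that may share reads. KO MET/CAT replicate 1 lay above WT MET/CAT replicate 1 for this list (mean log2 deviation 0.27 against 0.15), and the median was −0.50 without WT MET/CAT replicate 2. Macrophage markers had a median of 0.08 in the same comparison (adjusted p = 0.597). Cholesterol synthesis genes had a median of −0.47 over 24 measured, with none passing over the list alone (adjusted p = 7.74e-06; adjusted p = 0.752 with an estimated correlation). Lanosterol synthase Lss differed by −1.52, Nsdhl by −0.89 and Fdps by −1.86. Libraries of the groups overlapped (−0.31 to 0.41 in WT and −1.18 to −0.01 in KO MET/CAT), and without KO MET/CAT replicate 1 this call ended (−0.20, adjusted p = 0.0776). The median was −0.31 without WT MET/CAT replicate 2, −0.74 without WT MET/CAT replicate 3 and −0.71 without KO MET/CAT replicate 3.

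Immediate early genes, transcription factors and regulators switched on by stimulation, had a median of 1.08 over 18 measured in KO against WT MET/CAT livers (adjusted p = 7.74e-06; adjusted p = 0.485 with an estimated correlation). The list was led by Gadd45g (3.02), Zfp36 (1.63), Junb (2.11) and Btg2 (1.44), and none passed over the list alone. KO MET/CAT replicate 1 had a mean log2 deviation of 2.26 for this list against 0.47 and 0.32 in the other KO MET/CAT libraries, and the call ended without it (0.30, adjusted p = 0.107). Male-biased liver genes had a median of 0.60 over 19 measured, none passing over the list alone (adjusted p = 0.000318; adjusted p = 0.752 with an estimated correlation), led by C6 (1.67), Cyp2d9 (1.33), Slco1a1 (0.84) and Ugt2b38 (1.82). KO MET/CAT replicate 2 had a mean log2 deviation of 1.14 for this list against −0.49 and −0.86 in the other KO and −1.12 to −0.68 in the WT MET/CAT libraries, and the call ended without it (0.12, adjusted p = 0.274), while the median was 1.09 without KO MET/CAT replicate 3. Circadian clock genes had a median of 0.47 over 19 measured (adjusted p = 0.00269; adjusted p = 0.185 with an estimated correlation), and 2 rose when adjusted over the list alone. Bhlhe40 differed by 0.93, Usp2 by 1.75, Nfil3 by 1.05 and the repressor Nr1d1 by −1.97.

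In WT livers, MET/CAT was compared with GFP to ask what the oncogenes changed where Sirt2 was intact. The metallothionein Mt2, a zinc-binding protein, rose from 1536 ± 940 to 33410 ± 26500 normalized reads (SD, n = 3; 4.35, SE 0.50, adjusted p = 0.00515). Acod1, which makes itaconate in activated macrophages, had no read in the GFP livers and 332 in the MET/CAT livers. This was at least 118-fold higher by the floor (95% Poisson lower limit 95.4). The WT MET/CAT libraries ranged from 13.0 to 228.8 normalized reads of Acod1, and its call held in 2 of the 6 fits leaving out a library. Cyp2b10, a cytochrome P450 induced by drugs, rose from 44.3 ± 24.6 to 907.2 ± 844 (3.93), and the lipoprotein lipase gene Lpl from 1122 ± 317 to 5738 ± 2520 (2.29). The interleukin-1 receptor Il1r1 rose from 133.1 ± 23.9 to 997.3 ± 516 (2.73). The transcription factors Zbtb7c (3.20), Zbtb16 (3.14) and Spic (2.99), the last a regulator of macrophages, rose as well, as did Tacc2 (3.04) and Mid1 (2.26). The major urinary proteins Mup15 (−5.02), Mup19 (−4.50; 1561 ± 362 to 73.2 ± 34.4), Mup18 (−3.40) and Mup9 (−3.16) fell, although reads of these near-identical genes are uncertain. Nrep fell from 988.5 ± 645 to 75.1 ± 20.2 (−3.44) and transferrin, Trf, from 5738 ± 1360 to 1199 ± 237 (−2.25). The replication genes Mcm10 (−2.98; 1792 ± 368 to 236.9 ± 104) and Gmnn (−1.87), the proapoptotic gene Bmf (−2.72) and the clock gene Per3 (−2.65) fell too. The wider cell cycle list did not fall with Mcm10 and Gmnn, at a median of 0.40 with the length trend removed (camera adjusted p = 0.384).

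limma called 29 genes higher and 18 lower in this comparison, 46 of them by more than 1 log2 unit, edgeR 52 and 21, and DESeq2 341 and 207. With equal library totals, which moved the median of all genes from −0.01 to −0.12, the split was 27 higher and 44 lower. The count of 47 was 3 without WT GFP replicate 1, 4 without WT GFP replicate 2, 23 without WT MET/CAT replicate 3 and 373 without WT MET/CAT replicate 1. Mt2, Mup19 and Map3k6 kept their calls without each of the 6 libraries in turn, and Map3k6 was named after its values were seen. The calls of Trf, Zbtb7c and Mup9 each held in 1 of these 6 fits.

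Acute phase genes, the liver's secreted response to inflammation, were higher in MET/CAT than in GFP livers of WT mice. Of 23 measured, 1 rose over all genes and 16 rose when adjusted over the list alone, with a median of 0.91 (camera adjusted p = 1.59e-10; adjusted p = 0.419 with an estimated correlation). Beside Il1r1, the list was led by Lcn2 (3.71), fibrinogen Fga (1.43) and the cytokine feedback gene Socs3 (2.68), with adjusted p of 0.0696 to 0.077. WT MET/CAT replicate 1 stood apart, with a mean log2 deviation of −0.07 against 1.13 and 1.47 in the other WT MET/CAT libraries and −0.19 in WT GFP replicate 2. Neutrophil markers had a median of 1.56 over 13 measured, with 1 rising over all genes and 5 when adjusted over the list alone (adjusted p = 0.000124; adjusted p = 0.572 with an estimated correlation). The collagenase Mmp8 had no read in the GFP livers and 78 in the MET/CAT livers, at least 27.7-fold higher, and Retnlg (3.21), Cxcr2 (3.71) and S100a8 (2.35) followed. The call of Mmp8 held in 1 of the 6 fits leaving out a library. For neutrophil markers WT MET/CAT replicate 1 had 0.03 against 1.48 and 1.10. Their median was 2.55 without WT MET/CAT replicate 1 and 0.99 without WT MET/CAT replicate 2. Beta-catenin targets and pericentral genes had a median of 0.43 over 25 measured, 22 of them higher (adjusted p = 2.78e-05; adjusted p = 0.572 with an estimated correlation). The carboxylate transporter Slc13a3 rose over all genes (1.51, adjusted p = 0.0499) and 7 rose when adjusted over the list alone, led by Slc13a3, Glul, Axin2 and Tbx3 (1.45).

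Oncofetal and liver tumour markers had a median of 1.08 over 20 measured in WT livers, with 1 rising over all genes and 4 when adjusted over the list alone (adjusted p = 2.78e-05; adjusted p = 0.419 with an estimated correlation). Dlk1, a fetal liver protein, rose from 5 reads in the GFP livers to 184 in the MET/CAT livers (39.2-fold, 95% interval 16.5 to 122), and alpha-fetoprotein, Afp (2.14), Igf2 (1.82) and Ly6d (2.29) followed. Without WT MET/CAT replicate 1 the oncofetal median was 0.57. The call of Dlk1 held in 1 of the 6 fits leaving out a library. Male-biased liver genes had a median of −1.003 over 19 measured, and 5 fell when adjusted over the list alone (adjusted p = 2.83e-05; adjusted p = 0.624 with an estimated correlation). Mup11 differed by −2.80, Nudt7 by −1.62, Hsd3b5 by −4.02 and Cyp7b1 by −1.003. The female-biased Cyp2a4, a steroid hydroxylase, fell as well (−1.63, adjusted p = 0.0473). The labels give no sex, and every library held Xist, a marker of the inactive X, at 877.8 to 2300 normalized reads and the Y-linked Ddx3y at no more than 9.07. These values argue against a male library in any group.

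In KO livers, the same comparison asked what the oncogenes changed without Sirt2. Serum amyloid A genes rose, Saa1 from 231.9 ± 135 to 36100 ± 12400 normalized reads (SD, n = 3; 7.46, SE 0.92, adjusted p = 0.00406) and Saa2 from 106.7 ± 64.0 to 37300 ± 12700 (8.64, SE 1.09), as near-identical copies whose reads are uncertain. The cytokine Il1b rose 58.4-fold (95% interval 35.2 to 105), Acod1 419-fold against 1 read in the GFP livers (74.7 to 16600), and Timp1, an inhibitor of metalloproteinases, 27.0-fold (16.1 to 48.8). Over the KO MET/CAT libraries Il1b ranged from 91.0 to 594.9 and Acod1 from 38.7 to 305.9 normalized reads. A single library thus carried much of both folds, although their calls held in 6 and 5 of the 6 fits leaving out a library. The neutrophil attractant Cxcl1 (5.06; 33.7 ± 10.8 to 1414 ± 1210), Lcn2 (4.79), Socs3 (4.25), Mt2 (4.20; 2479 ± 693 to 45750 ± 13100) and the clock activator Arntl (4.02) rose. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 4476 ± 3210 to 590.7 ± 167 (−2.73, SE 0.41, adjusted p = 0.00741). Nrep (−3.50, 1394 ± 300 to 128.9 ± 57.1), Mup15 (−3.34), Mup19 (−3.25), Mup2 (−2.35), Clec2h (−3.23), Per3 (−2.75), the cell cycle kinase Wee1 (−2.72) and Zfp791 (−2.68) fell. Wee1 averaged 30.5 in WT GFP, 181.6 in KO GFP, 24.6 in WT MET/CAT and 23.9 in KO MET/CAT livers. Zfp791 averaged 10.8, 128.9, 57.5 and 24.4 in the same order. KO GFP was thus the high group for both genes. The calls of Wee1 and Zfp791 each held in 1 of the 6 fits leaving out a library.

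limma called 119 genes higher and 55 lower in KO livers, 161 of the 174 by more than 1 log2 unit, edgeR 122 and 80, and DESeq2 460 and 415. The split was 83 higher and 108 lower with equal library totals, which moved the median of all genes from 0.05 to −0.17, and 109 and 89 with quantile normalization. Without KO GFP replicate 1, 2 or 3 the counts were 67, 61 and 71, without KO MET/CAT replicate 1 or 2 they were 57 and 48, and with only the 6 libraries compared 84. Of the 174, 30 kept their call without each of the 6 libraries in turn, among them Saa1, Saa2, Il1b, Timp1, Socs3, Mt2, Nrep, Mup19, Mup2 and Cyp7a1.

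Inflammatory and immune lists were higher in KO MET/CAT than in KO GFP livers. Acute phase genes had a median of 1.06 over 23 measured, with 6 rising over all genes and 14 when adjusted over the list alone (camera adjusted p = 3.47e-11; adjusted p = 0.283 with an estimated correlation), among them Saa1, Saa2, Socs3 and orosomucoid Orm2 (2.83). With the length trend removed this median was 0.65. Cytokine and chemokine genes had a median of 1.60 over 20 measured, with 4 rising over all genes and 12 when adjusted over the list alone (adjusted p = 2.49e-08; adjusted p = 0.283 with an estimated correlation). These 4 were Il1b, Cxcl1, Ccl6 (1.62) and Ccl7, which rose 160-fold against 2 reads in the GFP livers (95% interval 43.8 to 1330). Ccl7 ranged from 16.7 to 258.9 normalized reads over the KO MET/CAT libraries, so that 1 library carried most of this fold. Its call held in 0 of the 6 fits leaving out a library. Neutrophil markers had a median of 3.38 over 13 measured, with 4 rising over all genes and 9 when adjusted over the list alone (adjusted p = 3.2e-07; adjusted p = 0.283 with an estimated correlation). S100a8 (3.63), S100a9 (3.97) and Mmp9 (28.9-fold, 95% interval 15.4 to 61.1) rose. Cxcr2 had no read in the GFP livers and 89 in the MET/CAT livers, at least 37.8-fold higher by the floor (95% Poisson lower limit 30.1). Over the KO MET/CAT libraries Mmp9 ranged from 17.8 to 202.3 and Cxcr2 from 6.28 to 83.1 normalized reads, so that 1 library carried much of each fold. Their calls held in 2 and 0 of the 6 fits leaving out a library. KO MET/CAT replicate 1 stood apart, with mean log2 deviations of 2.64 for cytokines against 0.32 and 0.71 in the other KO MET/CAT libraries, and of 2.70 for neutrophil markers against 0.47 and 0.93. Placing genes without reads at this bound left the medians of the cytokine and neutrophil lists as they were. Macrophage markers had higher values in 25 of 25 and a median of 1.19, with 2 rising over all genes, Laptm5 (1.49) and the scavenger receptor Marco (3.51), and 12 when adjusted over the list alone (adjusted p = 1.27e-09; adjusted p = 0.283 with an estimated correlation). Cd14 (2.60) and C1qa (1.83) followed, and the macrophage median was 0.64 without KO GFP replicate 3. C1qa averaged 686.8 ± 441 in KO GFP, 1933 ± 235 in KO MET/CAT and 2016 ± 378 in WT GFP livers.

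Further lists separated KO MET/CAT from KO GFP livers. Antigen presentation genes had a median of 0.45 over 16 measured (adjusted p = 0.000295; adjusted p = 0.427 with an estimated correlation), and the class II genes Cd74 (1.47), H2-Aa (1.39) and H2-Ab1 (1.26) rose, with 6 rising when adjusted over the list alone. H2-Eb1 differed by 1.5 (adjusted p = 0.0783), and the list's median was 0.23 with equal totals and 0.27 without KO GFP replicate 3. Cd74 averaged 1459 in WT GFP, 654.5 in KO GFP, 1447 in WT MET/CAT and 1703 in KO MET/CAT livers. H2-Aa averaged 527.7, 278.6, 544 and 678.5, and H2-Ab1 800.1, 395.4, 829 and 905.9, in the same order. KO GFP was thus the low group for each. The calls of Cd74, H2-Aa and H2-Ab1 held in 3, 1 and 1 of the 6 fits leaving out a library. Immediate early genes had a median of 1.36 over 18 measured, with 3 rising over all genes, Btg2 (2.86), Junb (3.71) and Jund (1.31), and 9 when adjusted over the list alone (adjusted p = 3.23e-05; adjusted p = 0.287 with an estimated correlation). Ier3 differed by 4.50 (adjusted p = 0.0894), and the median was 0.86 without KO MET/CAT replicate 1. Over the KO MET/CAT libraries Junb ranged from 1146 to 8095 and Btg2 from 689.4 to 3597 normalized reads. A single library thus carried much of both folds. The calls of Btg2, Junb and Jund held in 4, 1 and 1 of the 6 fits leaving out a library. Beta-catenin targets had a median of 0.78 over 25 measured, with Glul rising over all genes and 13 when adjusted over the list alone (adjusted p = 9.35e-05; adjusted p = 0.427 with an estimated correlation), followed by Lhpp (1.28), the glutamate transporter Slc1a2 (1.23) and the ammonium transporter Rhbg (2.33). The oncofetal list was not called here, with a median of 0.56 over 20 measured (adjusted p = 0.151) and 5 rising and 2 falling when adjusted over the list alone. Of its members, Dlk1 rose 151-fold against 2 reads in the GFP livers (95% interval 41.3 to 1250) and Ly6d rose by 3.36.

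Sterol and bile acid genes were lower in KO MET/CAT livers. Cholesterol synthesis genes had a median of −0.73 over 24 measured (adjusted p = 1.62e-06; adjusted p = 0.427 with an estimated correlation). The sterol carrier Stard4 fell over all genes (−1.44, adjusted p = 0.0268), and 7 fell and 1 rose when adjusted over the list alone, with Lss at −1.73, Nsdhl at −1.30 and Msmo1 at −1.46. KO MET/CAT replicate 3, at a mean log2 deviation of −0.01, lay above KO GFP replicate 1, at −0.07, and the median was −0.45 without KO MET/CAT replicate 1. Bile acid genes had a median of −0.15 over 20 measured (adjusted p = 0.00416; adjusted p = 0.283 with an estimated correlation). Cyp7a1 and the canalicular transporter Abcc2 (−1.06) fell, 3 fell when adjusted over the list alone, and Slc10a1 (−0.85) and Akr1d1 (−0.66) followed. The bile acid median was −0.39 under quantile normalization, −0.37 with equal totals, −0.24 with the length trend removed, and −0.23 and −0.25 without KO MET/CAT replicate 1 or 2. Single genes of other lists were called as well. The desaturase Fads2 (−0.95) and the glutathione synthesis gene Gclm (−0.78) fell, and pyruvate kinase Pkm (1.08), the lipid droplet gene Plin5 (1.74), the interferon-induced Mx2 (1.96) and the stress gene Nupr1 (2.58) rose. Of the 6 fits leaving out a library, the calls of Fads2 and Plin5 held in 0, that of Gclm in 1, and those of Pkm, Mx2 and Nupr1 in 2. Pkm averaged 604.8, 349.6, 662.6 and 733.1 in WT GFP, KO GFP, WT MET/CAT and KO MET/CAT livers. Gclm averaged 2373, 3836, 2343 and 2254 in the same order, so that KO GFP stood apart for both. Plin5 did not share this, at 584.2, 953, 2293 and 3108.

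Circadian clock genes differed between MET/CAT and GFP livers in opposite directions within the list. In WT livers the median over 19 measured was −0.64 (camera adjusted p = 0.00357; adjusted p = 0.248 with an estimated correlation), with Per3 falling over all genes, and 4 rising and 11 falling when adjusted over the list alone. The activator Arntl differed by 3.06 (18.5 ± 10.5 to 181.8 ± 119, SD, n = 3, adjusted p = 0.081), Nfil3 by 1.61, Tef by −1.66 and Dbp by −4.65 (2489 ± 374 to 245.8 ± 350, adjusted p = 0.0824). In KO livers Arntl (4.02) and Nfil3 (2.80) rose and Per3 (−2.75) fell over all genes, Dbp differed by −4.81 (adjusted p = 0.0527), and the list as a whole was not called (adjusted p = 0.0771). The hour at which livers were collected is not given in the sources used here.

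**Figure D2:**
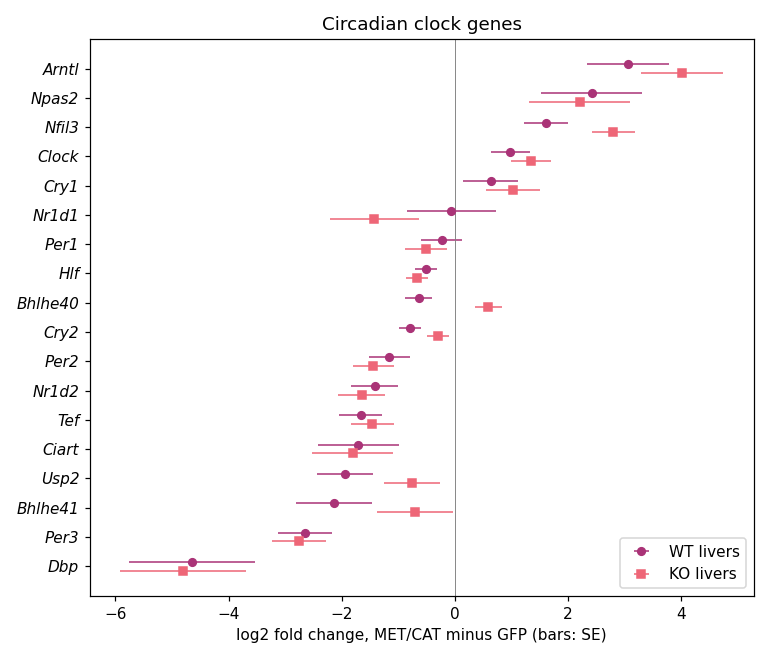
Log2 fold change of MET/CAT against GFP livers (horizontal axis) for 18 of the 19 measured clock genes in WT and KO livers, with bars of ± 1 SE of the limma fit over 12 libraries. Arntl lay at 3.06 and 4.02 and Dbp at −4.65 and −4.81 in WT and KO livers.

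Whether the response to MET/CAT depended on Sirt2 was tested by the interaction, the response in KO minus that in WT livers. limma and edgeR called 0 genes higher and 0 lower, with a smallest adjusted p of 0.19, and DESeq2 called 70 and 84, while 2153 genes had an unadjusted p under 0.05 against 693.6 by chance. The median SE was 0.467 log2 units. Among the genes with the smallest p, each at an adjusted p of 0.19, were Zfp791 (−5.01), Trf (3.63), the electron transfer flavoprotein Etfb (3.87) and the predicted gene Gm47283 (3.65), annotated on the Y chromosome although Y-linked genes were near 0 in every library. Trf averaged 5738 ± 1360 in WT GFP, 1226 ± 882 in KO GFP, 1199 ± 237 in WT MET/CAT and 2589 ± 335 in KO MET/CAT livers (SD, n = 3). Glul differed by 0.18 (adjusted p = 0.863) and Axin2 by −0.98 (adjusted p = 0.369) between the responses. Leaving out KO GFP replicate 2 gave 3 called genes, KO GFP replicate 3 gave 2, WT MET/CAT replicate 1 gave 3, WT MET/CAT replicate 3 gave 4 and KO MET/CAT replicate 3 gave 1.

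By gene list, 7 responses were higher and 4 lower in KO than in WT livers, and none was called with an estimated correlation (smallest adjusted p = 0.694). Macrophage markers had a median difference of 1.498 (camera adjusted p = 1.19e-06; adjusted p = 0.694 with an estimated correlation), with 6 of 25 rising when adjusted over the list alone, led by Laptm5 (1.66), Aif1 (1.80), C1qa (2.41) and Fcgr1 (1.70), and the median was 0.87 with the length trend removed and 0.85 without KO GFP replicate 3. Oxidative phosphorylation genes had a median difference of 0.75 over 38 measured, none passing over the list alone (adjusted p = 4.61e-07; adjusted p = 0.694 with an estimated correlation). Ndufb3 differed by 1.18, Ndufb10 by 1.40, Ndufs7 by 1.70 and Ndufa5 by 1.37. Log2 differences fell with transcript length here (rho = −0.368 across genes), and with the length trend removed the median was 0.25 (ordinary loess, adjusted p = 0.0241) and the call ended under robust loess (adjusted p = 0.0914). The median was 0.498 under quantile normalization and 0.44 without KO GFP replicate 3. Immediate early genes had a median difference of 1.002 over 18 measured, none passing over the list alone (adjusted p = 0.0174; adjusted p = 0.694 with an estimated correlation), led by Ier2 (1.81), Jund (0.97), Junb (2.48) and Ier3 (4.13). That call ended without WT MET/CAT replicate 1 (adjusted p = 0.0707) or KO MET/CAT replicate 1 (0.23, adjusted p = 0.314) and with length and GC content removed (adjusted p = 0.134), and its median was 0.64 with length alone removed. The number of lists called was 3 without WT MET/CAT replicate 1, 5 without KO MET/CAT replicate 1, and 7 without either WT GFP replicate 3 or KO GFP replicate 2, against 11.

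The responses in WT and KO livers shared called genes, and their fold changes had no library in common. Their tests used a variance per gene estimated over all 12 libraries, so the lists of called genes were not independent. The numbers given below for independent lists may therefore be too low as an expectation. Of the genes called higher, 9 were common to the 29 in WT and 119 in KO livers, where independent lists would share 0.249, and of those called lower 5 were common to 18 and 55, against 0.0714. The 9 included Acod1, Clpx, Cxcl13, Dlk1, Mid1, Mt2, Nedd4l and Spic, and the 5 were Fnip2, Mup15, Mup19, Nrep and Per3. No gene was called in opposite directions. Of the genes called in WT livers, 27 of 29 higher and 17 of 18 lower had the same sign in KO livers. Across all 13871 genes the log2 fold changes correlated at r = 0.226, a description across genes, which are not independent replicates. Leaving out each library gave 0.136 without KO GFP replicate 2 to 0.370 without KO GFP replicate 3 (jackknife SE 0.211).

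Averaged over GFP and MET/CAT livers, the genotype comparison asked what Sirt2 loss changed with either plasmid. Sirt2 fell by 2.16 (SE 0.16, adjusted p = 3.61e-05). Interferon response genes had lower values in 37 of 37 measured, of which 20 fell when adjusted over the list alone, with a median of −0.68 (camera adjusted p = 2.44e-19; adjusted p = 0.114 with an estimated correlation). Isg15 differed by −1.11 and Ifit3 by −1.27 (adjusted p = 0.0958 for both), Zbp1 by −1.13 and Ifit1 by −1.27. Isg15 averaged 759.4 ± 162, 321.8 ± 28.8, 734.0 ± 223 and 357.8 ± 56.1 in WT GFP, KO GFP, WT MET/CAT and KO MET/CAT livers (SD, n = 3). An exact permutation of the genotype within each plasmid, on the mean score of this list, gave a difference of −0.70 (p = 0.01, adjusted p = 0.12 over the lists) where 400 assignments allow no p under 0.005 and 1 list at that p alone adjusts to 0.18. Gluconeogenesis and glycogen genes had a median of 0.19 over 19 measured (adjusted p = 0.00131; adjusted p = 0.0837 with an estimated correlation), and the glycogen branching enzyme Gbe1 (0.53) rose when adjusted over the list alone. The median was 0.30 with equal totals and 0.11 without KO MET/CAT replicate 3. Igfbp1 (1.90), Pck1 (0.55) and Slc37a4 (0.30) followed, and the exact permutation of the list's score gave p = 0.005 and an adjusted p of 0.09.

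Beside Sirt2, limma called the histone gene Hist1h2bq in this average (3.83, adjusted p = 0.0454), with means of 1.13, 26.8, 0.332 and 14.5 in WT GFP, KO GFP, WT MET/CAT and KO MET/CAT livers. The WT libraries held 3 reads with GFP and 1 read with MET/CAT, so that the folds were 27.1 (95% interval 8.99 to 134) and 41.8 (7.08 to 1690), histone copies may share reads, and its call held in 2 of the 12 fits leaving out a library. edgeR called 0 genes higher and 1 lower here and DESeq2 15 and 23, while 1125 genes had an unadjusted p under 0.05. Without WT MET/CAT replicate 3 limma called 11 genes.

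**Figure D3:**
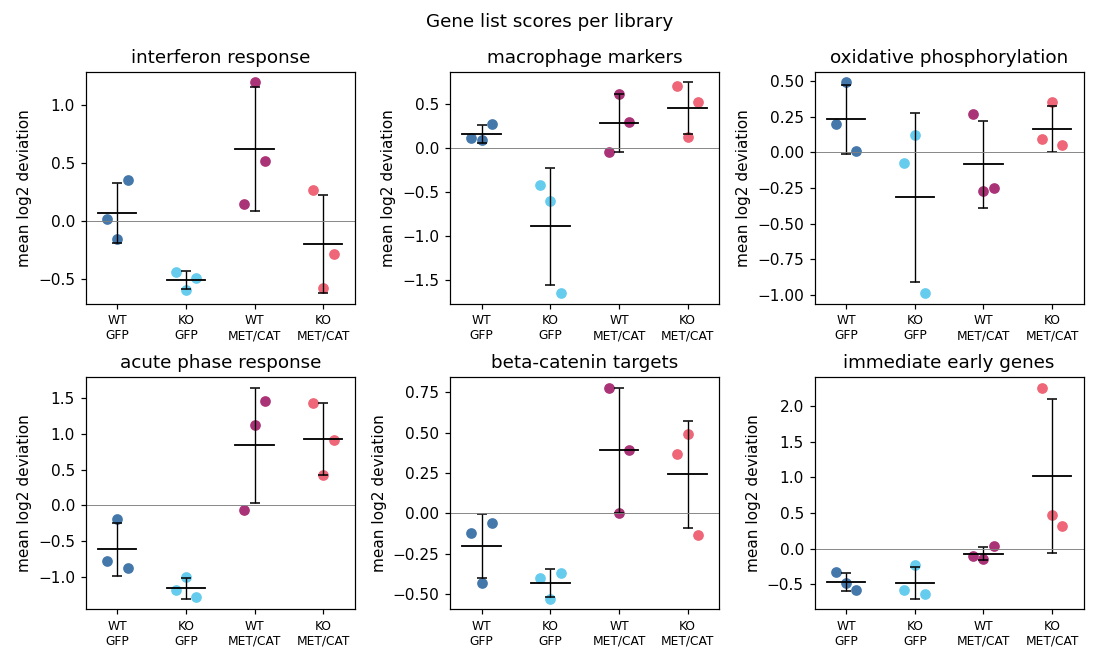
Mean log2 deviation from each gene's mean over 12 libraries (vertical axes) for the interferon, macrophage, oxidative phosphorylation, acute phase, beta-catenin and immediate early lists, with points for libraries, lines for group means and bars for ± 1 SD (n = 3). KO GFP replicate 3 lay at −1.65 for macrophage markers and at −0.99 for oxidative phosphorylation, and KO MET/CAT replicate 1 at 2.26 for immediate early genes.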

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

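Of the tests in this part, the splits of the libraries and the permutation of list scores had their predictions written before their results, the permutation having been added after the data were seen, and all other tests were chosen after the result was seen. The list tests of the interaction, which compare the MET/CAT response in KO livers with that in WT livers, picked out 11 lists. Median differences were 1.5 for macrophage markers (adjusted p = 1.19e-06), 0.752 for oxidative phosphorylation (adjusted p = 4.61e-07), 0.492 for antigen presentation (adjusted p = 0.0174), 0.959 for cytokines and chemokines (adjusted p = 0.0476) and 1 for immediate early genes (adjusted p = 0.0174). They were 1.27 for T and NK cell markers (adjusted p = 0.0279), 0.398 for endothelial markers (adjusted p = 0.0174), −1.06 for the cell cycle (adjusted p = 0.000179) and −0.499 for cholesterol synthesis (adjusted p = 0.0174). They were −0.347 for bile acid genes (adjusted p = 0.0189) and −0.194 for fatty acid oxidation and PPARA targets (adjusted p = 0.0266). With the length trend removed by ordinary loess, the calls of cytokines (0.51, adjusted p = 0.215) and T and NK cell markers (0.88, adjusted p = 0.166) ended, and medians were 0.87 for macrophage markers, 0.25 for oxidative phosphorylation, 0.27 for antigen presentation (adjusted p = 0.0499), 0.64 for immediate early genes, 0.67 for endothelial markers and −0.45 for fatty acid oxidation. The call of immediate early genes ended with length and GC content removed (adjusted p = 0.134), that of antigen presentation there too (adjusted p = 0.143) and under robust loess (adjusted p = 0.0654), that of oxidative phosphorylation under robust loess (adjusted p = 0.0914), and that of cytokines with a pseudocount of 8 (adjusted p = 0.0667) or a filter of 50 (adjusted p = 0.112). Only the macrophage, oxidative phosphorylation and cell cycle lists kept their calls without each library in turn, with medians of 0.85, 0.44 and −0.69 without KO GFP replicate 3, while the cytokine median was 0.21 without KO MET/CAT replicate 1 (adjusted p = 0.916). The calls of all 11 lists carry little weight, since 62 of 100 splits, the real one included, called at least as many lists as the real 11 (highest other 25). In addition, none was called with an estimated correlation.

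Other splits of the same libraries show how far the counts depend on which libraries share a group. Each number of splits below includes the real one and counts splits with at least as many calls. For genes, the real split called the most in GFP livers (KO against WT, 1 of 10 splits with as many, highest other 0), in WT livers (MET/CAT against GFP, 1 of 10, highest other 0 against 47) and in KO livers (1 of 10, highest other 0 against 174). With 10 splits no share under 0.05 is possible. In MET/CAT livers 2 of 10 splits called at least as many genes as the real 1, namely the real split and 1 that called 64. In the average over plasmids 9 of 100 called at least the real 2, and the highest other called 71. These high counts point to structure among the libraries other than genotype. For the interaction 100 of 100 splits called at least the real 0, with a highest other of 11. That share was fixed in advance, since no count can lie under 0, and it decides nothing. For lists, as many were called in 2 of 10 splits for KO against WT in GFP livers (15, highest other 18), 10 of 10 in MET/CAT livers (8, highest other 19), 4 of 10 for MET/CAT in WT (12, highest other 20), 4 of 10 in KO livers (17, highest other 20) and 18 of 100 in the average (15, highest other 25). List calls at the preset correlation therefore carry little weight in any comparison.

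The lower macrophage markers and oxidative phosphorylation genes of KO GFP livers were weighed against the length trend and against KO GFP replicate 3. With each library's length trend removed, the oxidative phosphorylation median went from −0.54 to −0.0843 (adjusted p = 0.182; 0.292 as the adjusted p with robust loess and 0.0493 with length and GC content), so that the length trend could account for it, and to −0.215 without KO GFP replicate 3 (adjusted p = 0.0302), which leaves open how much of it this library carries. The macrophage median went from −1.25 to −0.895 with the length trend removed (adjusted p = 1.68e-10) and to −0.744 without KO GFP replicate 3 (adjusted p = 2.26e-10), which argues against either as its only source. These p-values rest on camera's preset correlation, and the length trend and KO GFP replicate 3 were not removed together. A lower share of all other cell types would lower stellate cell and matrix markers too, but these lay 1.25 (SE 0.464) above the macrophage markers. Markers of T and NK cells (−1.10, a call that ended under robust loess at an adjusted p of 0.0509), B and plasma cells (−0.74, or −0.426 with the length trend removed) and endothelium (−0.32, adjusted p = 0.04) had lower medians as well, in calls that each ended without at least 1 library, and the erythroid call ended with the length trend removed (−1.10 to −0.509, adjusted p = 0.214), so that a lower share of several cell types, of macrophages alone, or lower expression in them, remains open.

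Clock genes differed between MET/CAT and GFP livers in WT and KO mice. A set of 5 genes with Arntl had medians of 1.61 in WT and 2.21 in KO livers, and a set of 9 genes with Dbp had −1.66 and −1.46, a difference of 3.47 averaged over genotypes. The matching difference of set means, computed per library, had an SE of 0.646, which is not the SE of the medians. The sets were picked after the values were seen and leave out other members such as Per1, Cry2, Bhlhe40 and Bhlhe41, so this does not decide whether a different clock phase at collection is the source, and the 14 members outside the Arntl set had medians of −1.29 and −1.09. With the length trend removed the difference of medians was 3.53 (SE of the difference of set means 0.645), which argues against transcript length. The hour of collection is not given in the sources used here, and an effect of the tumours or of inflammation on the clock was not tested.

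Interferon response genes were lower in KO livers with either plasmid. If fewer macrophages were the source, their markers would fall at least as far, but in MET/CAT livers they lay 0.98 (SE 0.166) above the interferon genes, which argues against it there, and in GFP livers −0.468 (SE 0.399) leaves it open. The median went from −0.68 to −0.60 with the length trend removed (adjusted p = 6.48e-20), which argues against length. The exact permutation of the genotype, adjusted over the lists, gave 0.12, but 1 list at the smallest possible p alone adjusts to 0.18, so that this test decides nothing about a chance assignment. An effect of Sirt2 in hepatocytes on interferon signalling may be the source, but no test here separates it from other differences between the mice.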

How the results depend on the processing

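Of the settings in this part, the removals of the length trend and the exact permutation of list scores were chosen after the data were seen. Sirt2 kept its direction under every setting. With library quality weights the genes called were 4575 and 2 for KO against WT in GFP and MET/CAT livers, 2615 and 1635 for MET/CAT against GFP in WT and KO livers, 1374 for the interaction and 160 for the average. Under these weights Mcm5 (−0.0459) and Mcm6 (−0.143) reversed in GFP livers. In the same order DESeq2 called 108, 35, 548, 875, 154 and 38 genes. edgeR called 73 in the WT response, 46 of them shared with limma, and 1 in the average. The WT response held 81 genes under quantile normalization and 71 with equal totals. The length trend removed gave 135 (ordinary loess), 123 (robust) or 131 (with GC content) in the WT response, 269 in the KO response (ordinary) and 3 for KO against WT in GFP livers (robust). With only the 6 libraries compared, 0 genes were called for KO against WT in GFP livers, where the call of Sirt2 ended, and 84 in the KO response. In the average, a pseudocount of 0.5 left 1 gene and a filter of 50 left 1. The cause was not tested for any of these.

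The replicate numbers are not stated to pair animals, and 5 of 18 same-number pairs of libraries correlated above 0.1 (−0.195 to 0.28). With a replicate block, 7 genes were called for KO against WT in GFP livers, 2 in the interaction and 1 in the average.

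With an estimated correlation 0 lists were called in each of the 6 comparisons, and with the exact permutation, where 1 list at the smallest possible p alone adjusts to 0.18, 0 in the average. In the interaction 7 lists were called with robust loess and 7 with length and GC content removed. Leaving out each library in turn gave 1 to 10 and 0 to 12 genes for KO against WT in GFP and MET/CAT livers, 3 to 373 and 48 to 132 for the WT and KO responses, 0 to 4 for the interaction and 1 to 11 for the average. For lists the ranges were 9 to 18, 7 to 12, 10 to 14, 16 to 19, 3 to 15 and 13 to 19. The correlation of the responses ranged from 0.136 to 0.370. A group with a library left out had fewer samples, and this lowers the power.

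Over all settings, the named genes kept direction and side of the threshold in 589 of 639 cases for KO against WT in GFP livers, 509 of 519 in MET/CAT livers, 701 of 876 and 975 of 1215 for the WT and KO responses, 421 of 450 for the interaction and 247 of 274 for the average. A gene that was not called and stayed so counts as kept. Sirt2 was the single called gene for KO against WT with either plasmid, and no gene was called in the interaction. High shares there therefore say little about stability and cannot be set against those of the responses. Calls were lost in 107 and 202 cases of the responses. Depth limits genes near a few reads, since a count of 0 allows up to 3.61 normalized reads in a library.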

Other observations

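The observations in this part were picked after the results were seen, and so were the removals of the length trend. Other lists separated the groups by camera at its preset correlation, and each call in this paragraph ended without at least 1 library. In KO against WT GFP livers, T and NK cell markers had a median of −1.10 (adjusted p = 0.0107, or 0.0561 as the adjusted p without KO GFP replicate 3 and 0.0509 with the length trend removed by robust loess). B and plasma cell markers had −0.74 (adjusted p = 0.0229, or 0.101 without KO GFP replicate 2), and −0.43 with the length trend removed. Erythroid genes had −1.10 (adjusted p = 0.0253, or 0.119 without KO GFP replicate 2), but −0.51 with the length trend removed, where the call ended (adjusted p = 0.214). Fatty acid oxidation and PPARA targets had 0.33 (adjusted p = 0.00206, or 0.194 without WT GFP replicate 3). The sirtuin list had a median of −0.50 (adjusted p = 0.0371), or −0.07 without KO GFP replicate 3 (adjusted p = 0.0861) and −0.27 with the length trend removed. Sirt2 was the single called member of 7, with Sirt5 at −0.58 and Sirt1 at 0.22. In KO against WT MET/CAT livers, oxidative phosphorylation genes had a median of 0.25 (adjusted p = 0.00245, or 0.0736 without WT MET/CAT replicate 2), opposite in sign to the GFP livers, and 0.16 with the length trend removed, a call that ended under robust loess (adjusted p = 0.123). Female-biased genes had −0.55 (adjusted p = 0.0368), with Cyp17a1 at −1.50 and Sult2a2 at −4.08, but −0.03 without KO MET/CAT replicate 2 (adjusted p = 0.977), whose mean log2 deviation was −1.81 against 0.68 and 0.05 in the other KO MET/CAT libraries.

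In MET/CAT against GFP livers of WT mice, cytokines had a median of 1.24 (adjusted p = 0.00024), or 0.43 without WT MET/CAT replicate 2, and unfolded protein response genes 0.35 (adjusted p = 0.00627), a call that ended without WT MET/CAT replicate 3 (adjusted p = 0.212). In KO mice, cell cycle genes had a median of −0.85 (adjusted p = 5.99e-05), or −0.33 without KO MET/CAT replicate 1, and cholangiocyte markers 1.08 (adjusted p = 0.00878), or 0.60 without KO GFP replicate 3. Endothelial markers had 0.45 (adjusted p = 0.000275) and glycolysis genes 0.44 (adjusted p = 0.00612), a call that ended with length and GC content removed (adjusted p = 0.06). No list in either paragraph was called with an estimated correlation.

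Saa1 averaged 1130 ± 962 in WT GFP, 231.9 ± 135 in KO GFP, 17570 ± 14900 in WT MET/CAT and 36100 ± 12400 in KO MET/CAT livers (SD, n = 3). The WT MET/CAT libraries ranged from 1471 to 30730.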
